A study of Mus musculus with 9 samples.

How the data were processed

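RNA-seq was done on naive CD4+ T cells of the mouse, sorted as CD4+CD62LhighCD44low and stimulated for 24 h with antibodies to CD3 and CD28, per the labels. The labels name 3 groups of 3 libraries: control (wild type), Fosl2 Tg (overexpression) and Fosl2 KO. Libraries were directional and made from poly-A RNA, per the labels' protocols. The labels do not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

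TopHat, Cufflinks and Cuffdiff and the mouse genome build mm10 are named in the submitters' processing notes; their versions, settings, strand option and gene annotation are not given in the sources used here. The authors deposited FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) per gene and library, per the file headers, and these values were used as deposited. Of the genes listed, 23849 had an entry, and every library column was matched to a sample by its name (0 unmatched). The authors also deposited a table of their Cuffdiff comparisons with FPKM per group, log2 fold changes, p-values and q-values, per the file headers. That table holds 4122 entries, all significant in at least 1 comparison, and its group values were normalized separately from the values per library. It was used only as a comparison and for no test. An entry without content in each deposited table was not analysed here. Spreadsheet software had turned 27 gene symbols into dates, of which 15 were tested without a usable name.

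FPKM does not give counts, so no count model was used. Depth was estimated from the lowest values: a gene with few fragments takes FPKM values in whole steps, and the size of a step falls with depth. Of 4875 genes with every FPKM below 1 and at least 4 libraries above 0, 40.1% had all values within 0.05 of whole multiples of a step, so counts could not be recovered gene by gene. Relative depth came from the ratios between libraries, and absolute depth from 262 of these genes with a single annotated transcript of at least 2000 bases. Estimated depth was 31.6 to 56.9 M fragments (M, 10 to the power of 6). Approximate fragments per gene follow from it and cover counting error only. MicroRNA, small nucleolar and small nuclear RNA genes held 21.1% to 37.9% of the summed FPKM of a library, because FPKM of very short genes is inflated.

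Values were analysed as log2(FPKM + 1). Genes with a mean FPKM of at least 1 over the 9 libraries were tested (10340, of which 169 were small RNA genes). Fold changes on this scale understate the change of genes with low FPKM. All 9 libraries entered 1 fit in limma 3.58.1 with a trend of variance on mean and no covariate (6 residual degrees of freedom), and adjusted p-values are Benjamini-Hochberg values from limma over all genes of a comparison, with 0.05 as the threshold. Means are given with the SD of 3 libraries and fold changes with the standard error (SE) from limma. Fosl2 and Foxp3 were also tested with a two-sided exact permutation test, which cannot go below p = 0.1 for 3 against 3 libraries. Chance gives non-overlapping groups for 10% of genes in this design.

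Lists of genes were fixed before the data were examined: 26 lists with 466 symbols, 15 of them not found. They cover regulatory T cell (Treg), Th1, Th2, Th17, follicular helper, AP-1, T cell activation, naive and quiescence, IL-2 and STAT5 response, type I interferon, TGF-beta, co-inhibitory receptor, migration, apoptosis, cell cycle, glycolysis, cholesterol synthesis, ribosome biogenesis and heat shock genes. Markers of CD8 T cells, B cells, myeloid cells, NK and gamma delta T cells, red blood cells, memory and effector T cells and stroma completed them. Lists with at least 5 measured members (21) were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives.

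Genes named in the text followed a rule that was also fixed before the data were examined. For each genotype against control these were Fosl2, Foxp3, the 10 higher and the 10 lower genes with the largest change among those past the threshold with non-overlapping groups, and up to 4 called members of each list with the smallest adjusted p. For Fosl2 Tg against the libraries labelled Fosl2 KO the rule took 5 genes per direction, and for opposite changes the 10 with the largest smaller change. Predicted genes, pseudogenes, small RNA genes, antigen receptor segments and entries of several genes were left out of naming. Symbols that occur more than once in the table (79 tested entries) were left out as well, an exclusion added to the rule after seeing the table. Genes named outside the rule are marked as such. A result that the rule selected is not reported here.

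Relations between the 2 comparisons against control were set beside 100 simulated pairs of unchanged groups that share the control libraries. Positions refer to mm10 and count from 1. Deposited starts count from 0, since 7636 of 21922 genes started 1 base below the GENCODE vM21 annotation and 769 at the same base. Foxp3 overlaps Flicr on its own strand and Ccdc22 on the other, and Il2 overlaps Adad1, Cd160 overlaps Pdzk1, Tnfrsf9 overlaps Camta1 Cxcr6 overlaps Fyco1 and Cdc20 overlaps Elovl1 on the other strand. Irf8 overlaps Gm20388 and Ifitm2 overlaps Gm45717 on their own strand; since the strand option is not given, such genes may share fragments. H2-Q6, Ly6a, Ly6c1, Ly6c2, Ifitm2 and histone genes belong to families of near-identical copies, and their values are uncertain.

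The alternatives were another pseudocount, other filters, median-of-ratios and quantile scaling, a replicate block, only the groups compared, limma without trend, array weights, each library left out in turn and, chosen after seeing the data, the small RNA genes left out. The fit was tested on simulated data with 10340 genes and 200 changed genes. For Fosl2 Tg against control it recovered 91% of genes changed 1.5-fold, 94% at 2-fold and 100% at 4-fold, with 6 false calls among 196. For the libraries labelled Fosl2 KO against control it recovered 86.6%, 97% and 93.9%, with 7 false calls among 192. A list shifted by -0.5 in simulated data passed camera (adjusted p = 8.39e-50), and 0 of the other lists did. Genes were simulated independently of each other, and the changed genes were not drawn from those with the lowest control levels. The simulation therefore does not cover lists whose members vary together, nor the recovery of genes with the lowest levels. Computations ran in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.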

Results

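Gene expression was measured in stimulated naive CD4+ T cells from control mice, from mice overexpressing Fosl2 (Fosl2 Tg) and from a group labelled Fosl2 KO, with 3 libraries each. Fosl2 encodes a member of the AP-1 family of transcription factors. Estimated depth was 45.8, 44.9 and 50.4 M fragments (M, 10 to the power of 6) in the control libraries, 39.2, 49.3 and 56.9 M in Fosl2 Tg, and 31.6, 42.3 and 56.7 M in the libraries labelled Fosl2 KO. Correlations of log2(FPKM + 1) were 0.924 to 0.951 between libraries of 1 group and 0.901 to 0.959 between groups. On the principal component with the largest share of variance (24%), Fosl2 Tg library 1 lay farthest from the centre, at -49.4. The correlations and the component include the 169 small RNA genes and were not computed without them, so they may not reflect the other genes.

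Fosl2, the targeted gene, was higher than control in both other groups. Fosl2 (chromosome 5, 32136472 to 32157839) had an FPKM of 7.77, 7.44 and 6.15 in the control libraries, a mean of 7.12 ± 0.856 (SD, n = 3). Fosl2 Tg had 30.9, 19.2 and 24.5, a mean of 24.9 ± 5.84 (SD, n = 3), and rose by 1.65 ± 0.15 (log2, SE, limma adjusted p = 0.000749). The libraries labelled Fosl2 KO had 19.2, 17.8 and 17.1, a mean of 18 ± 1.09 (SD, n = 3), and rose by 1.23 ± 0.15 (limma adjusted p = 0.00404). Fosl2 therefore went against the KO label, and every direction given below for the libraries labelled Fosl2 KO belongs to libraries with a higher, not a lower, total Fosl2 FPKM. An FPKM per gene does not show which exons were transcribed, so a transcript without part of the gene would not be seen. Fosl2 Tg exceeded the libraries labelled Fosl2 KO by 0.42 ± 0.15 (limma adjusted p = 0.0594), which did not pass the threshold. Without Fosl2 Tg library 2 this difference was 0.58 and passed (limma adjusted p = 0.0129), and without Fosl2 Tg library 1 it was 0.26. The exact permutation test gave p = 0.1 for each pair of groups, the smallest it can give.

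Foxp3, the lineage transcription factor of regulatory T cells named in the series title, moved in opposite directions in the 2 genotypes. Foxp3 (chromosome X, 7579676 to 7595243) had a mean FPKM of 2.55 ± 0.422 in control, 0.391 ± 0.164 in Fosl2 Tg and 6.31 ± 0.150 in the libraries labelled Fosl2 KO (SD, n = 3 each). It fell by 1.35 ± 0.11 (log2, SE) in Fosl2 Tg (limma adjusted p = 0.000341). It rose by 1.05 ± 0.11 in the libraries labelled Fosl2 KO (limma adjusted p = 0.00155). Fosl2 Tg lay below the libraries labelled Fosl2 KO by a log2 difference of -2.40 ± 0.11 (limma adjusted p = 4.25e-06). These levels correspond to about 391 to 532 fragments per control library, 47 to 102 in Fosl2 Tg and 755 to 1410 in the libraries labelled Fosl2 KO. The exact permutation test again gave p = 0.1 for each pair, the smallest possible, and fragments of the overlapping genes Flicr and Ccdc22 cannot be separated from those of Foxp3 here.

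**Figure D1:**
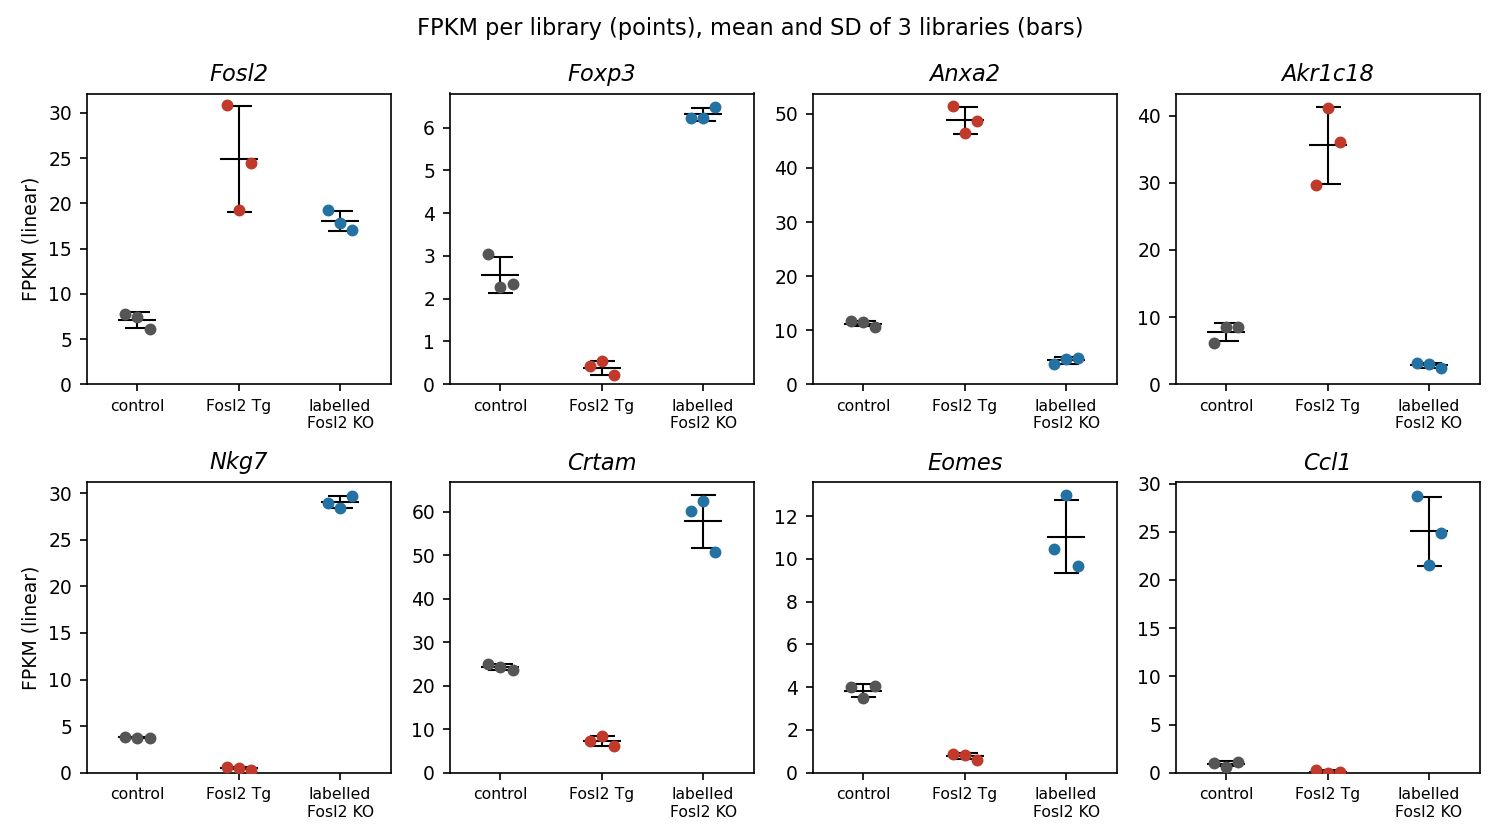
FPKM (linear axis from 0) of 8 genes in each library (points), with the mean and SD of 3 libraries per group (bars). Fosl2 was highest in Fosl2 Tg (mean 24.9) and higher in the libraries labelled Fosl2 KO (18) than in control (7.12), while Foxp3 was lowest in Fosl2 Tg (0.391) and highest in the libraries labelled Fosl2 KO (6.31).

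Fosl2 Tg was compared with control to find what overexpression of Fosl2 changed. The calcium-binding protein gene S100a6 rose from 0.463 ± 0.0240 to 10.2 ± 3.17 FPKM (SD, n = 3; log2 2.90 ± 0.17, limma adjusted p = 8.17e-05), and its relative S100a11 rose from 66.9 ± 1.2 to 208 ± 17.5 (1.62 ± 0.07). Anxa2, a calcium-dependent membrane-binding protein, rose from 11.2 ± 0.524 to 48.8 ± 2.47 (2.03 ± 0.08, limma adjusted p = 1.91e-05). The secreted protease gene Prss12 (2.70 ± 0.17), the hydroxysteroid dehydrogenase gene Akr1c18 (2.07 ± 0.15) and the arginine deiminase gene Padi2 (1.73 ± 0.16) also rose. The activation marker Cd83 fell from 7.08 ± 0.779 to 0.905 ± 0.135 (log2 -2.08 ± 0.11, limma adjusted p = 4.35e-05). The cytotoxic granule gene Nkg7 fell from 3.79 ± 0.0701 to 0.490 ± 0.139 (-1.69 ± 0.07), the adhesion molecule gene Crtam from 24.3 ± 0.651 to 7.31 ± 1.18 (-1.62 ± 0.11), and the chemokine receptor gene Ccr8 from 6.84 ± 0.231 to 1.69 ± 0.418 (-1.56 ± 0.11). Ifitm2 (-2.06), Farp1 (-1.84), Plk2 (-1.75), Marcksl1 (-1.62), Lad1 (-1.57) and the receptor kinase gene Axl (-1.56) completed the 10 lower genes with the largest changes. H2-Q6 (3.58 against 0.153 FPKM), Ly6a and Ly6c2 were among the 10 higher genes with uncertain values. Ly6c2 stood at 43.6 FPKM in Fosl2 Tg library 1 against 7.23 and 7.84 in the others, and Ly6a at 42.6 against 10.7 and 16.2; the Ly6a call was lost without control library 2 (limma adjusted p = 0.0618) or 3 (0.0721).

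In total, 2440 of 10340 genes passed limma's threshold, 882 higher and 1558 lower in Fosl2 Tg. Of these, 40 were more than 2-fold higher and 73 more than 2-fold lower on the log2(FPKM + 1) scale. The 2 groups did not overlap for 45.2% of tested genes, against 10% by chance. Higher genes made up 36.1% of the calls, but 46.5% (1100 higher, 1265 lower) after median-of-ratios scaling and 45.5% (1062 higher, 1271 lower) after quantile normalization. Without control library 2 the calls numbered 879, without control library 3 1142, and without library 2 or 3 of those labelled Fosl2 KO, which share the estimate of spread, 1615 and 1497.

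Genes of the cell cycle were lower as a group in Fosl2 Tg. Of 30 cell cycle genes, 27 fell and none rose over all genes tested, and 29 fell when adjusted over the list alone (median log2 change -0.80). The proliferation marker Mki67 fell from 19.2 ± 1.04 to 8.88 ± 1.80 FPKM (SD, n = 3), the mitotic kinase gene Aurkb from 22.9 ± 3.56 to 9.30 ± 1.74, and Cdc20 from 13.3 ± 1.79 to 7.09 ± 0.855. The list passed camera (adjusted p = 7.57e-11), but had an adjusted p = 0.641 with an estimated correlation. Ribosome biogenesis genes were lower as well: 7 of 25 fell and 0 rose (12 adjusted over the list alone; median -0.26), with a camera adjusted p of 0.000228 and an adjusted p = 0.641 with an estimated correlation. Of 20 glycolysis genes, 9 fell and 2 rose (13 and 2 adjusted over the list alone). The lactate transporter gene Slc16a3 fell from 4.33 to 2.46 FPKM and Egln3 rose from 1.41 to 3.52, and the list had a camera adjusted p of 0.0148 and an adjusted p = 0.641 with an estimated correlation.

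Naive and quiescence genes were higher as a group in Fosl2 Tg: 7 of 24 rose and 0 fell, and 13 rose when adjusted over the list alone (median 0.51). Igfbp4 rose from 52.2 ± 1.60 to 97.6 ± 7.14 FPKM (SD, n = 3), the lymph node homing receptor gene Ccr7 from 323 ± 2.42 to 412 ± 6.09, and Actn1 from 90.5 ± 5.20 to 133 ± 19.8. The naive list passed camera (adjusted p = 4.32e-06), with an adjusted p = 0.641 with an estimated correlation. Of 26 T cell activation genes, 11 fell, among them the growth factor gene Il2 (160 ± 18.9 to 62.5 ± 14.4 FPKM) and Irf8 (22.6 ± 1.74 to 13.6 ± 2.23), and 2 rose (14 and 3 adjusted over the list alone). The activation list did not pass camera (adjusted p = 0.0837), but the alternative fry called it lower (adjusted p = 0.0052). The number of list members past the test depended on the control libraries. Without control library 2 it was 15 lower for cell cycle, 0 for ribosome biogenesis, 1 lower for glycolysis, 3 higher for naive and 6 lower for activation genes. Without control library 3 it was 15, 0, 4, 3 and 8. Naive genes past the test numbered 12 without Fosl2 Tg library 2 and 4 without any 1 of the libraries labelled Fosl2 KO. Ribosome biogenesis genes numbered 4 without Fosl2 Tg library 1 or 3 or any 1 of the libraries labelled Fosl2 KO. Activation genes numbered 7 lower without library 2 of those labelled Fosl2 KO, and glycolysis genes 5 lower without its library 3.

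Genes of T helper and regulatory T cells moved in mixed directions in Fosl2 Tg. Of 9 Th1 genes, 5 fell, among them the transcription factor gene Eomes (3.84 to 0.773 FPKM) and the chemokine gene Ccl3 (8.08 to 2.90), while the granzyme gene Gzmb rose (1.15 to 4.52), with the same counts adjusted over the list alone. The Th1 list had a camera adjusted p of 0.0232 and an adjusted p = 0.641 with an estimated correlation, and did not pass without Fosl2 Tg library 1 (0.0577) or 2 (0.0564) or with array weights (0.118). Of 5 CD8 T cell markers, Nkg7, Eomes and Ctsw fell, genes that effector CD4 T cells also express, while Cd8b1 was at 11.8 in control and 11.7 in Fosl2 Tg. The CD8 list had a camera adjusted p of 0.0287 and an adjusted p = 0.641 with an estimated correlation, and did not pass without control library 1 (0.057) or Fosl2 Tg library 1 (0.0577) or 2 (0.0602), without a filter on low values (0.054) or with array weights (0.138). Of 14 Treg genes, 6 fell, among them Foxp3, the inhibitory receptor gene Ctla4 (58.3 to 27.0) and Tnfrsf18 (144 to 85.3), and 4 rose, among them Nt5e (2.72 to 5.75), Capg (86.2 to 123) and Rgs16 (30.7 to 50.6). Adjusted over the list alone, 7 Treg genes fell and 4 rose, and the list did not pass (camera adjusted p = 0.477). Fewer than 6 Treg genes fell whichever library was left out. They numbered 4, 3 and 4 without control library 1, 2 and 3, and 5, 5 and 4 without Fosl2 Tg library 1, 2 and 3. Without library 1, 2 and 3 of those labelled Fosl2 KO they numbered 5, 4 and 4.

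No other list passed camera in Fosl2 Tg against control. Memory and effector T cell markers split into 6 higher, with S100a6, Anxa2 and Lgals1, and 4 lower, with Nkg7 and Cxcr6, of 13 (6 and 5 adjusted over the list alone). Of 16 IL-2 and STAT5 response genes, 5 rose and 3 fell (6 and 4 adjusted over the list alone). Without control library 2, 3 of them rose, and 1 fell without any 1 control library or library 3 of those labelled Fosl2 KO. The kinase gene Pim1 rose from 74.7 to 127 FPKM, and Bcl2l1 fell from 106 to 65.4. Apoptosis genes gave 3 higher and 7 lower of 26 (4 and 11 adjusted over the list alone), with Bcl2l11 higher and Pmaip1 lower. Without control library 2 or 3, 2 apoptosis genes fell, and 4 without Fosl2 Tg library 1 or 2. Of 14 AP-1 genes other than Fosl2, Jun (4.10 to 2.35), Junb (112 to 91.0) and Jund (123 to 97) fell and Atf2 rose, a call that was lost whichever of the 9 libraries was left out. Among Th2 genes, 3 of 7 rose and Ccr8 fell, with a median of -0.03 although camera pointed upward. The call of Gata3, 1 of these 3, was lost without control library 2 or 3 or Fosl2 Tg library 1 or 2. It was also lost without any 1 of the libraries labelled Fosl2 KO. Higher and lower members numbered 1 and 1 of 7 for Th17, 1 and 2 of 10 for follicular helper, 2 and 3 of 13 for interferon, 3 and 2 of 14 for TGF-beta and 1 and 3 of 9 for co-inhibitory receptor genes. They numbered 3 and 3 of 17 for migration, 0 and 1 of 21 for cholesterol synthesis and 1 and 0 of 9 for heat shock genes. Interferon genes numbered 1 and 1 without control library 2, and 1 rose without control library 3, Fosl2 Tg library 3 or any 1 of the libraries labelled Fosl2 KO. The higher co-inhibitory receptor gene lost its call without any 1 control or Fosl2 Tg library or library 3 of those labelled Fosl2 KO. Counts of 1 moved as well: Th17 genes numbered 2 higher without control library 1, 0 higher without control library 3 and 0 lower without control library 2 or Fosl2 Tg library 3, follicular helper genes 2 higher without control library 2 or Fosl2 Tg library 1, and cholesterol synthesis genes 2 lower without control library 1 or Fosl2 Tg library 2. Lists with fewer than 5 measured members were not tested as a group: of the B cell markers Cd74 fell (15.3 to 6.71 FPKM), of 3 stromal markers Epcam rose and Thy1 fell, of 3 myeloid markers Ly6c2 was higher, a call lost without any 1 control library or library labelled Fosl2 KO (limma adjusted p 0.0663 to 0.134), the 1 NK and gamma delta marker did not pass, and no red blood cell marker was measured.

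The libraries labelled Fosl2 KO were compared with control to find what differed in that genotype, with the reservation that total Fosl2 FPKM was higher in them. The chemokine gene Ccl1 rose from 0.932 ± 0.269 to 25.1 ± 3.57 FPKM (SD, n = 3; log2 3.75 ± 0.15, limma adjusted p = 1.39e-05), and the chemokine gene Xcl1 from 14.7 ± 3.51 to 39.2 ± 4.15 (1.37 ± 0.18). Nkg7 rose from 3.79 ± 0.0701 to 29.0 ± 0.676 (2.65 ± 0.07, limma adjusted p = 1.19e-06), and the calmodulin-binding protein gene Nrgn from 1.11 ± 0.197 to 12.5 ± 1.46 (2.68 ± 0.11). The enolase gene Eno3 (1.72 ± 0.08), the nuclear receptor gene Nr4a2 (1.67 ± 0.11) and Wnt10b (1.64 ± 0.21) rose, as did Idi2 (1.87), Cap2 (1.54) and Mcoln2 (1.39). Anxa2 fell from 11.2 ± 0.524 to 4.42 ± 0.619 (-1.18 ± 0.08) and Akr1c18 from 7.75 ± 1.33 to 2.86 ± 0.364 (-1.17 ± 0.15). The death-domain adaptor gene Unc5cl fell from 3.57 ± 0.110 to 0.709 ± 0.351 (-1.44 ± 0.15), and Ubtd1 from 7.19 ± 0.264 to 3.10 ± 0.303. Cpne8, the lower gene with the largest change (29.1 ± 5.96 to 9.83 ± 4.81; -1.54 ± 0.32), Rgs1 (64.9 to 28.2), Dapl1 (46.5 to 21.8), Plek (8.04 to 3.50) and Sema7a (6.74 to 2.89) fell as well, but each of these 5 calls was lost without control library 2 or 3 or library 1 or 2 of those labelled Fosl2 KO. Cpne8, Plek and Sema7a also lost theirs without control library 1, Dapl1 and Sema7a without library 3 of those labelled Fosl2 KO, and Cpne8 without Fosl2 Tg library 3.

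In total, 461 of 10340 genes passed limma's threshold, 221 higher and 240 lower in the libraries labelled Fosl2 KO. Of these, 27 were more than 2-fold higher and 8 more than 2-fold lower on the log2(FPKM + 1) scale. The 2 groups did not overlap for 32.8% of tested genes, against 10% by chance. The calls numbered 272, 176 and 313 without control library 1, 2 and 3 in that order, 191, 178 and 210 without library 1, 2 and 3 of those labelled Fosl2 KO, and 1233 without Fosl2 Tg library 1, which enters only the estimate of spread.

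Called genes were more frequent near Fosl2 on chromosome 5. Actr3b, an actin-related protein gene 6.34 Mb away, rose from 0.630 ± 0.0410 to 3.78 ± 0.416 FPKM (SD, n = 3; log2 1.55 ± 0.08, limma adjusted p = 6.16e-05). With Fosl2 left out, 16 of 121 tested genes within 10 Mb of it passed (13.2%), against 444 of 10218 other genes (4.35%; one-sided Fisher's exact test p = 8.72e-05). Outside the naming rule and chosen after their values were seen, Galnt11 (4.71 to 13.8 FPKM) and Srpk2 (9.77 to 17.7) rose, and AI506816 (19.1 to 9.44) and Mrpl33 (125 to 85.1) fell. In Fosl2 Tg, 25 of the same 121 genes passed, against 2414 of 10218 (one-sided Fisher's exact test p = 0.807).

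**Figure D2:**
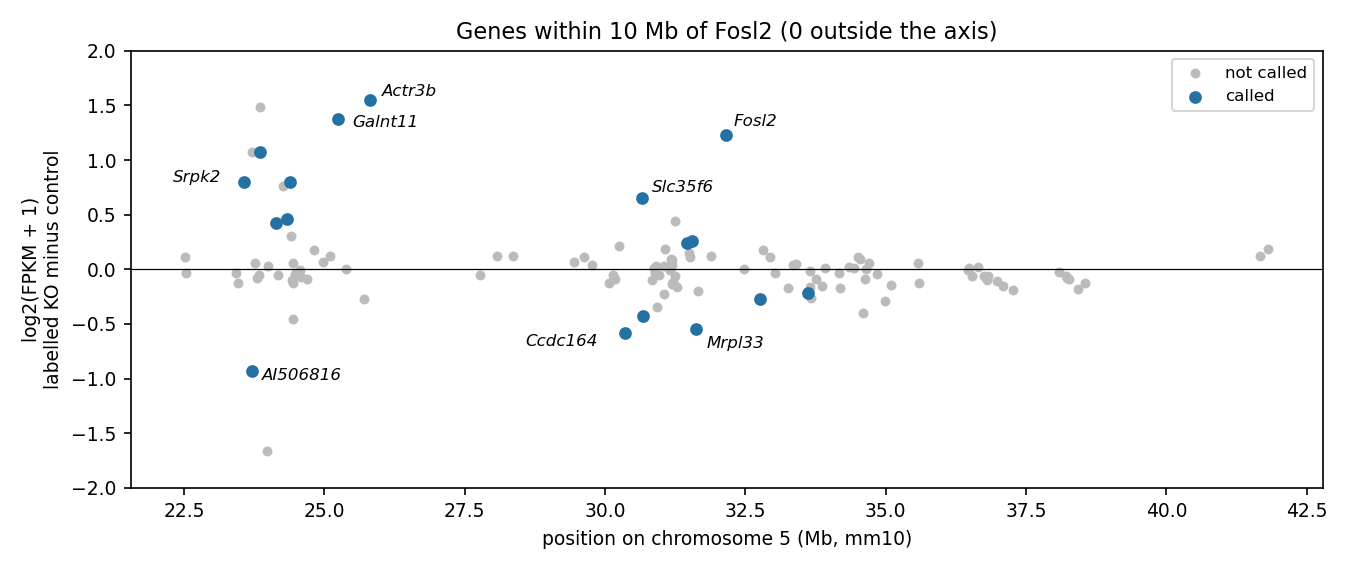
Log2 change in FPKM + 1 of the libraries labelled Fosl2 KO against control (y axis) for tested genes within 10 Mb of Fosl2, by position on chromosome 5 in Mb (x axis, mm10); filled blue points passed limma's threshold. The 16 called genes other than Fosl2 include Actr3b (1.55) and Galnt11 (1.38) above 0 and AI506816 (-0.93) below.

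T helper and activation genes included members higher in the libraries labelled Fosl2 KO. Of 9 Th1 genes, Nkg7, Xcl1 and Eomes (3.84 ± 0.312 to 11 ± 1.72 FPKM; SD, n = 3) rose. Adjusted over the list alone, 3 rose and 2 fell, and the list passed camera (adjusted p = 0.00569), with an adjusted p = 0.418 with an estimated correlation. Of 5 CD8 T cell markers, Nkg7, Eomes and Ctsw (4.37 to 10.7 FPKM) rose, but Cd8b1, a chain of the CD8 co-receptor, fell (11.8 to 6.63). The CD8 list passed camera (adjusted p = 0.0116), with an adjusted p = 0.418 with an estimated correlation, and did not pass without Fosl2 Tg library 1 (0.116), without a filter on low values (0.281), with a pseudocount of 0.1 (0.0751), with only the groups compared (0.11) or with array weights (0.167). Of 26 activation genes, Nr4a2 (8.90 to 30.4), Tnfrsf9 (70.9 to 138), Irf8 (22.6 to 44.4) and Cd44 (19.4 to 29.7) rose and 1 fell. Adjusted over the list alone, 7 rose and 5 fell, and the list did not pass (camera adjusted p = 0.103). Without Fosl2 Tg library 1, 8 activation genes rose and 6 fell. Of 14 Treg genes, Foxp3 and Lrrc32 (1.03 to 2.33) rose and Capg (86.2 to 54.9) and Nt5e (2.72 to 1.03) fell (3 and 3 adjusted over the list alone). The Treg list did not pass (camera adjusted p = 0.858), and its median (-0.11) and mean (0.004) differed in sign.

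Naive genes and IL-2 and STAT5 response genes were lower as groups, and cell cycle genes passed camera downward without a separation of the libraries. Of 24 naive genes, 4 fell and 0 rose (5 adjusted over the list alone; median -0.29), among them the transcriptional regulator gene Id3 (158 ± 12 to 87.3 ± 2.65 FPKM; SD, n = 3) and Igfbp4 (52.2 ± 1.60 to 25.7 ± 2.63). The naive list had a camera adjusted p of 0.000283 and an adjusted p = 0.73 with an estimated correlation. Of 16 IL-2 and STAT5 response genes, 3 fell, among them Pim1 (74.7 ± 3.95 to 39.1 ± 4.74), and 0 rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.00504, adjusted p = 0.678 with an estimated correlation). Of 30 cell cycle genes, 1, E2f2, fell (9.75 to 6.37; median of the list -0.19), and the list had a camera adjusted p of 0.00504 and an adjusted p = 0.798 with an estimated correlation. Relative to the control mean, the median of the cell cycle genes was -0.37, -0.08 and -0.15 in the libraries labelled Fosl2 KO and -0.17, 0.04 and 0.14 in control. Control library 1 thus lay below 2 of the 3 libraries labelled Fosl2 KO. Taken by replicate number, each library labelled Fosl2 KO lay below its control, though the labels do not say that the numbers pair samples. The cell cycle list did not pass without control library 3 (0.0664), and E2f2 itself did not pass without control library 2 or 3 or library 1 or 3 of those labelled Fosl2 KO. Without Fosl2 Tg library 1, 11 naive genes fell. Without control library 2 or 3 or any 1 of the libraries labelled Fosl2 KO, 2 naive genes fell, and 1 of the IL-2 and STAT5 genes fell without control library 2 or any 1 of the libraries labelled Fosl2 KO.

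Cholesterol synthesis and ribosome biogenesis genes passed camera upward with no member past the test alone. None of 21 cholesterol synthesis genes passed limma's threshold over all genes, and 2 rose when adjusted over the list alone (median 0.07; camera adjusted p = 0.00504, adjusted p = 0.73 with an estimated correlation). Without Fosl2 Tg library 1, 4 of them rose. None of 25 ribosome biogenesis genes passed, over all genes or over the list alone (median 0.07; camera adjusted p = 0.0283, adjusted p = 0.842 with an estimated correlation). Its call was lost without control library 1 (0.416) or library 1 of those labelled Fosl2 KO (0.122), without a filter on low values (0.0788) and with array weights (0.0502).

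No other list passed camera in the libraries labelled Fosl2 KO. Higher and lower members numbered 2 and 0 of 7 for Th2 genes, with Ccr8 higher (6.84 to 15.4), and 2 and 0 of 9 for co-inhibitory receptor genes, Pdcd1lg2 (6.90 to 12.7) and Cd160 (4.24 to 8.44). They numbered 2 and 0 of 13 for interferon genes, with the RNA sensor gene Ifih1 higher (3.56 to 8.12), and 2 and 0 of 20 for glycolysis genes, with Slc16a3 higher (4.33 to 8.41). They numbered 1 and 3 of 14 for TGF-beta genes, with Tgfb1 lower (78.8 to 62.7), 1 and 1 of 26 for apoptosis genes (3 and 8 adjusted over the list alone), Tnfsf10 higher and Fasl lower, and 3 and 3 of 13 for memory and effector markers. They numbered 1 and 0 of 10 for follicular helper and 2 and 3 of 17 for migration genes, and 0 of 14 AP-1 and 0 of 9 heat shock genes passed. Without Fosl2 Tg library 1, 8 migration and 4 apoptosis genes fell; without any 1 of the libraries labelled Fosl2 KO, 0 migration genes fell. TGF-beta genes numbered 1 lower without control library 1 or 2, Fosl2 Tg library 3 or library 1 or 2 of those labelled Fosl2 KO. Interferon genes numbered 1 higher without any 1 control library, Fosl2 Tg library 3 or any 1 of the libraries labelled Fosl2 KO. Without any 1 of the libraries labelled Fosl2 KO, 1 Th2, 1 glycolysis and 0 follicular helper genes were higher. The same counts came without control library 2 or 3 for Th2, control library 2 for glycolysis and control library 1 for follicular helper genes. Migration genes numbered 0 lower without control library 1 or 2 or Fosl2 Tg library 3, and 1 without control library 3 or Fosl2 Tg library 2. Of the lists too small to test, the NK and gamma delta marker Prf1 rose (0.513 to 1.92), and no B cell, myeloid or stromal marker passed.

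**Figure D3:**
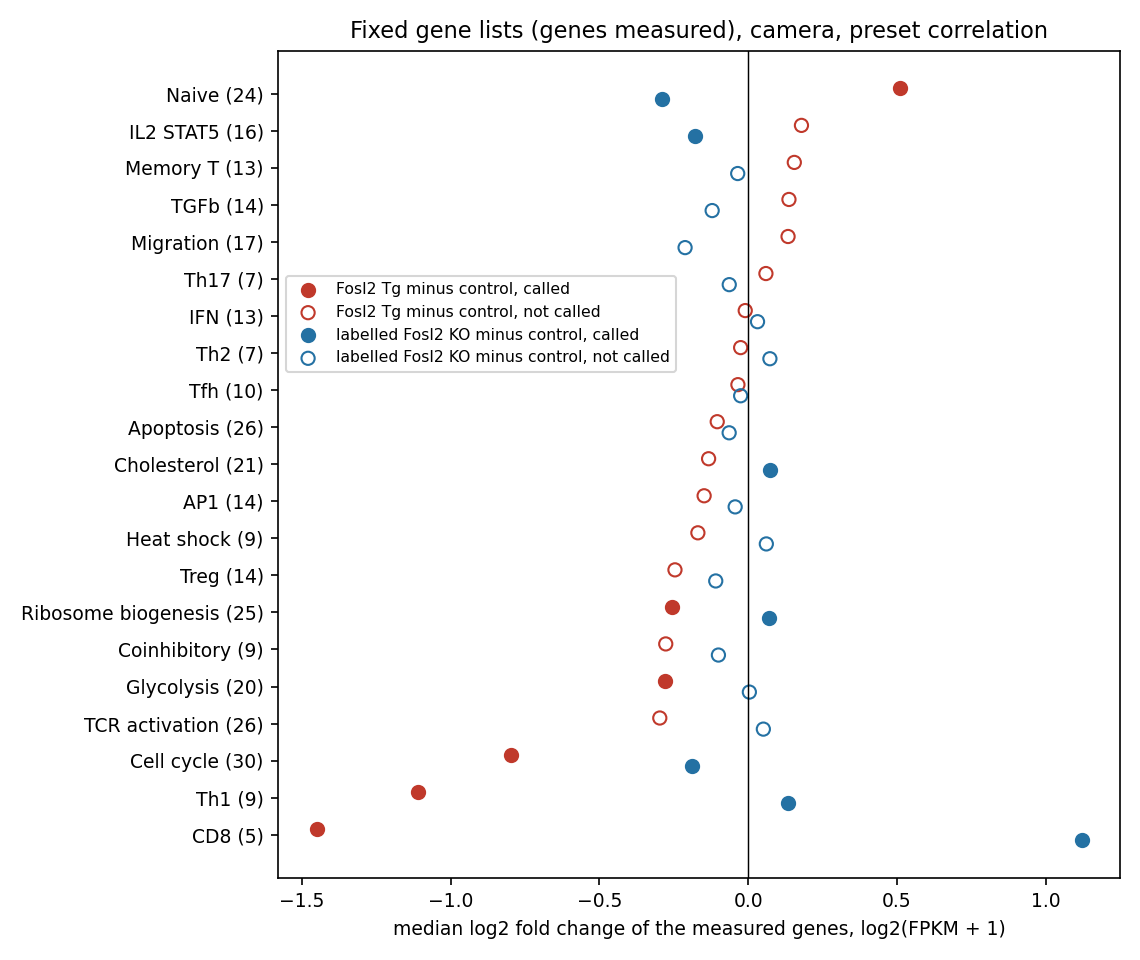
Median log2 change in FPKM + 1 of the measured members of each tested list (number of members in parentheses), for Fosl2 Tg against control (red) and the libraries labelled Fosl2 KO against control (blue); filled points passed camera at the preset correlation. Naive genes lay at 0.51 in Fosl2 Tg and -0.29 in the libraries labelled Fosl2 KO, and cell cycle genes at -0.80 and -0.19.

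Fosl2 Tg was set against the libraries labelled Fosl2 KO directly. In this comparison control libraries enter only the estimate of spread, and both groups had a higher total Fosl2 FPKM than control. Anxa2 (48.8 ± 2.47 against 4.42 ± 0.619 FPKM; SD, n = 3; log2 3.21 ± 0.08, limma adjusted p = 5.81e-07), Akr1c18 (3.24 ± 0.15), S100a6 (3.07 ± 0.17) and Prss12 (3.03 ± 0.17) were higher in Fosl2 Tg. Ly6c1 was also higher (3.17 ± 0.63), at 156.7, 23.5 and 26 FPKM in the Fosl2 Tg libraries. Ccl1 (0.114 ± 0.156 against 25.1 ± 3.57; -4.55 ± 0.15), Nkg7 (-4.34 ± 0.07, limma adjusted p = 2e-08), Nrgn (-3.48 ± 0.11), Crtam (-2.83 ± 0.11) and Eno3 (-2.81 ± 0.08) were lower. In total, 3943 genes passed, 1801 higher and 2142 lower in Fosl2 Tg, with 165 and 123 of them changed more than 2-fold on the log2(FPKM + 1) scale. The groups did not overlap for 60.4% of tested genes, against 10% by chance.

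Of 24 naive genes, 18 were higher and 0 lower in Fosl2 Tg than in the libraries labelled Fosl2 KO (19 adjusted over the list alone; camera adjusted p = 3.34e-08). Of 30 cell cycle genes 23 were lower (26 adjusted over the list alone; 3.13e-06), of 25 ribosome biogenesis genes 20 (25; 1.13e-05) and of 21 cholesterol synthesis genes 11 (14; 0.0052), with 0 higher in each. Th1 genes (2 higher, 5 lower of 9), IL-2 and STAT5 genes (8 and 2 of 16) and glycolysis genes (1 and 10 of 20) each had a camera adjusted p of 0.0183. The glycolysis call was lost after quantile normalization (0.0761). TGF-beta genes (6 and 3 of 14) had 0.0481 and lost the call in 12 of 19 alternatives. These were each control library left out (0.0541, 0.0571 and 0.059), library 1 (0.0711) or 2 (0.0627) of those labelled Fosl2 KO left out, no filter (0.391), median-of-ratios scaling (0.0603), quantile normalization (0.0761), only the groups compared (0.0713), no trend (0.0537), array weights (0.0566) and no small RNA genes (0.0514). For each of these 8 lists the adjusted p = 0.593 with an estimated correlation. The calls numbered 2578, 2170 and 2343 without library 1, 2 and 3 of those labelled Fosl2 KO. In the same order, 18, 8 and 8 cell cycle genes and 4, 6 and 7 ribosome biogenesis genes were lower. Cholesterol synthesis genes numbered 5 and 4 lower without library 1 or 2, and ribosome biogenesis genes 13 without control library 2. Glycolysis genes numbered 6 lower without library 1 or 3 of those labelled Fosl2 KO. No other list passed, among them Treg (4 higher, 8 lower of 14) and activation genes (7 higher, 13 lower of 26).

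Opposite changes against control were more common than changes in the same direction among genes called in both genotypes (189 against 39), except with array weights (1507 against 1800). Nkg7, Crtam, Eomes, Ctsw, Xcl1, Eno3, Ccr8 and Foxp3 fell in Fosl2 Tg and rose in the libraries labelled Fosl2 KO, while Anxa2 and Akr1c18 rose and fell. Fosl2 rose in both. Of 228 genes called in both comparisons, 82 were higher in Fosl2 Tg and lower in the libraries labelled Fosl2 KO, and 107 the reverse, against 20.5 and 33.3 for independent lists. In the same direction, 8 were higher and 31 lower in both, against 18.9 and 36.2 for independent lists. Both comparisons share the 3 control libraries. The 189 opposite genes numbered 106, 77 and 120 without control library 1, 2 and 3, 95, 86 and 97 without library 1, 2 and 3 of those labelled Fosl2 KO, and 415 without Fosl2 Tg library 1.

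Over all 10340 genes, which are not independent replicates, the 2 sets of log2 changes had a Pearson correlation of 0.309 and a Spearman correlation of -0.08. The Spearman correlation turned positive without control library 1 (0.144) and with array weights (0.031), and the Pearson correlation was 0.16 without Fosl2 Tg library 3. Unchanged groups that share the controls gave a Pearson correlation of 0.493 on average in 100 simulations (0.268 to 0.710). The covariance was 0.0572, against 0.0509 simulated. Without the small RNA genes, a choice made after seeing the data, the Pearson correlation over 10171 genes was -0.20 and the covariance -0.0126, against 0.00541 simulated.

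**Figure D4:**
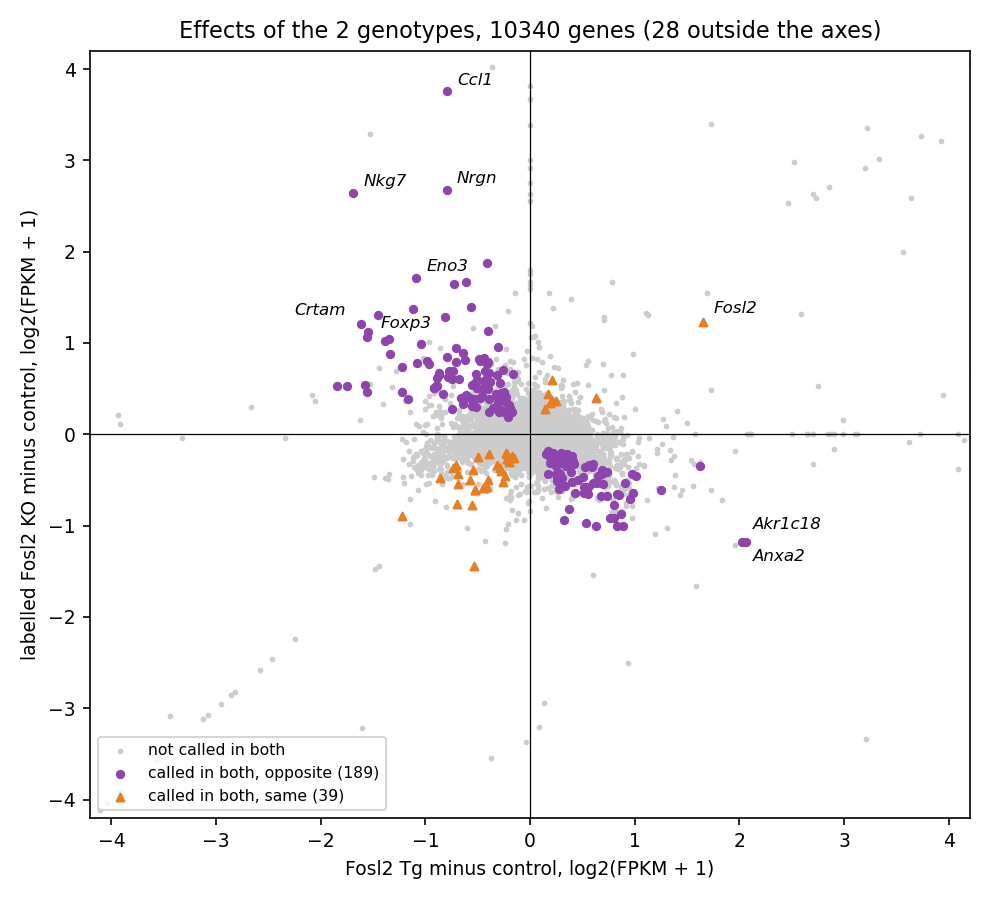
Log2 change in FPKM + 1 against control of each tested gene in Fosl2 Tg (x axis) and in the libraries labelled Fosl2 KO (y axis); 28 genes lie outside the axes. Of the genes called in both comparisons, 189 changed in opposite directions (purple circles) and 39, Fosl2 among them, in the same direction (orange triangles).

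In the authors' deposited table, Fosl2 was higher than control by a log2 fold change of 1.84 in Fosl2 Tg and 1.34 in the libraries labelled Fosl2 KO, and the entry that joins Foxp3 with a neighbouring transcript changed by -2.02 and 1.22, each with a q-value of 0.000503. The authors' deposited table lists q-values below 0.05 for 2678 genes in Fosl2 Tg (1478 higher, 1200 lower) and 1150 in the libraries labelled Fosl2 KO (534 higher, 616 lower). Of the 2430 and 459 genes with a unique symbol that limma called, 1760 and 410 are in the authors' deposited table. Of these, 1529 and 363 have a q-value below 0.05 and the same direction there. In Fosl2 Tg most of the authors' calls were higher, while most of limma's were lower.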

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

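The fit without small RNA genes was chosen after seeing the data; the other alternatives were fixed before. Fosl2 and Foxp3 kept their direction and stayed past limma's threshold against control in each alternative that gave a value, with log2 changes of 1.42 to 1.82 and 1.14 to 1.33 for Fosl2 in Fosl2 Tg and the libraries labelled Fosl2 KO, and of -2.48 to -1.24 and 0.99 to 1.29 for Foxp3. A mean FPKM of at least 5 removed Foxp3 from testing. Estimated depth (31.6 to 56.9 M fragments) leaves 47 to 102 fragments for Foxp3 in Fosl2 Tg. No named gene reversed when a library was left out, but 17 of 83 named calls in Fosl2 Tg and 18 of 57 in the libraries labelled Fosl2 KO fell below the threshold without some library.

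With only the groups compared in the fit, 861 genes were called in Fosl2 Tg (287 higher, 574 lower), against 2440 in the shared fit. In the libraries labelled Fosl2 KO the calls rose to 888 (367 higher, 521 lower), against 461. Fewer libraries estimate the spread in these fits, which alone does not account for this rise. The larger number of calls in Fosl2 Tg than in the libraries labelled Fosl2 KO therefore depended on the shared estimate of spread. With array weights the calls numbered 5991 (2370 higher, 3621 lower) and 5313 (2104 higher, 3209 lower), with 3215 lower in Fosl2 Tg against the libraries labelled Fosl2 KO. The weights were estimated without convergence, and control library 2 got a weight of 18.1 against 0.408 and 0.228 for the other controls. A mean FPKM of at least 5, with fewer genes tested, gave 289 calls in the libraries labelled Fosl2 KO (115 higher), and no filter gave 353 higher there.

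No list passed with an estimated correlation in any comparison (0, 0 and 0 lists), while fry, which tests each list alone, called 10, 5 and 12. Fry did not call ribosome biogenesis (adjusted p = 0.0514) in Fosl2 Tg, nor naive (0.0587), cholesterol synthesis (0.229), cell cycle (0.371) and ribosome biogenesis genes (0.556) in the libraries labelled Fosl2 KO. Unlike camera, it called activation (0.0052), co-inhibitory receptor (0.0245), apoptosis (0.0245) and AP-1 genes (0.027) lower in Fosl2 Tg. Memory and effector markers it called higher in Fosl2 Tg (0.0145) and, with Th2 genes (0.0399), in the libraries labelled Fosl2 KO (0.0447). Fosl2 Tg exceeded the libraries labelled Fosl2 KO in Fosl2 by 0.419 past the threshold without small RNA genes (adjusted p = 0.0445) and by 0.286 with array weights (adjusted p = 0.0265); over all alternatives the adjusted p ran from 0.0129 to 0.156, and the cause was not tested.

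The Pearson correlation between the effects reversed to -0.204 without small RNA genes, whose removal is the only change in that fit. With array weights it was 0.593 (Spearman 0.031), with 1507 opposite and 1800 same-direction genes. A mean FPKM of at least 5 gave 118 and 23. The cause was not tested for array weights.

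Leaving out 1 library at a time gave 879 to 2529 calls in Fosl2 Tg (321 to 939 higher, 558 to 1590 lower), 176 to 1233 in the libraries labelled Fosl2 KO (97 to 497 higher, 75 to 736 lower) and 2170 to 4100 between the genotypes (1071 to 1871 higher, 1099 to 2229 lower). Fosl2 differed between the genotypes by 0.256 to 0.584. The correlations ran from 0.16 to 0.439 (Pearson) and from -0.248 to 0.144 (Spearman), with 77 to 415 opposite and 8 to 99 same-direction genes. Fewer libraries accompany each of these fits; the rise to 1233 came without Fosl2 Tg library 1, and the cause was not tested.

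Over all tested genes, small RNA genes among them, the replicate numbers showed no pairing. Same-numbered libraries deviated together with correlations of -0.126 to 0.0985, and 0 of 9 pairs were over 0.1. Of the 9 libraries, 1 correlated best with its own number. Yet library 1 had the lowest cell cycle median in every group. This median was -0.17 in control, -1.06 in Fosl2 Tg and -0.37 in the libraries labelled Fosl2 KO. Pairing is therefore not excluded. With the replicate number as a block, calls numbered 3259, 491 and 4589, against 2440, 461 and 3943 without it. Same-direction genes numbered 77, and the Th1 and CD8 lists in Fosl2 Tg lost their calls (camera adjusted p = 0.0692 and 0.0763). Fosl2 between the genotypes was 0.419 (limma adjusted p = 0.0324).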

Other observations

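The histone genes, the chromosome bins, the test of activation genes against cell cycle genes, the repeat without Galnt11 and Actr3b and the counts over other splits of the libraries were chosen after the results were seen. Of 33 histone genes tested, 31 of them on chromosome 13, 25 fell and 0 rose in Fosl2 Tg against control (median log2 change -0.81), and 1 fell in the libraries labelled Fosl2 KO (median -0.24). Against the libraries labelled Fosl2 KO, 21 were lower and 1 higher in Fosl2 Tg. Relative to the control mean, the median of these genes was -0.99, -0.69 and -0.64 in the Fosl2 Tg libraries. Most histone transcripts lack a poly-A tail and their copies are near-identical, so these values are uncertain. Of 239 bins of 10 Mb, the bin from 20000001 to 30000000 on chromosome 13 had 32 of 55 tested genes called in Fosl2 Tg (adjusted p = 9e-06), and a bin from 120000001 on chromosome 3 had 13 of 22 (adjusted p = 0.0452). In the libraries labelled Fosl2 KO no bin passed, and the lowest adjusted p (0.0907) belonged to the bin from 20000001 on chromosome 5, with 9 of 53, and to the start of chromosome 17, with 7 of 35.

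Fosl2 was higher in the libraries labelled Fosl2 KO than in control. If DNA around a targeted allele caused the calls near Fosl2, a swap of the control and KO labels would place Fosl2 Tg nearer to the libraries labelled Fosl2 KO there. Fosl2 Tg lay nearer to control for 87.5% of these genes (14 of 16). Of all 461 genes called in the libraries labelled Fosl2 KO, 69.0% had the opposite sign in Fosl2 Tg, which also places Fosl2 Tg nearer to control. At most of the 16 genes near Fosl2, however, the sign was the same in both, so this does not explain their position. The 14 of 16 speak against a swap only if DNA around a targeted allele caused these calls. That cause is not settled, so the test does not decide whether the labels were swapped. Transcription from a targeted allele that keeps part of the gene, or a response of Fosl2 to loss of its own protein, may raise its FPKM, and both stay open as untested, since no value per exon was at hand. No other technical explanation was tested.

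The libraries labelled Fosl2 KO had more called genes near Fosl2 than elsewhere (one-sided Fisher's exact test p = 8.72e-05). DNA around a targeted allele that stems from another mouse strain is a candidate explanation: it predicts such an excess, which Fosl2 Tg against control did not show (p = 0.807 in the same exact test). It also predicts an excess in Fosl2 Tg against the libraries labelled Fosl2 KO. There 55 of 121 genes within 10 Mb passed (45.5%), against 38.1% of other genes, which missed the threshold (same exact test p = 0.0589). Within 2, 5 and 20 Mb the exact p was 0.152, 0.229 and 0.0369. Without Galnt11 and Actr3b, seen among the calls before the test was planned, 14 of 119 genes passed (exact p = 0.000766). By distance from Fosl2, 8 of 45 tested genes passed within 2 Mb, 8 of 77 within 5 Mb and 16 of 121 within 10 Mb. The largest changes were not the closest, with Actr3b 6.34 Mb and Galnt11 6.9 Mb away. No sequence variant was examined, so a regional effect of the altered allele on its neighbours stays open as well.

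Cell cycle genes were lower in Fosl2 Tg. At least 29 of 30 genes lay below the control mean in each Fosl2 Tg library, but so did 29 in control library 1 and 28 in library 1 of those labelled Fosl2 KO, so this count does not separate the groups. What argues against a single divergent library is that the median was -1.06, -0.78 and -0.58 in the Fosl2 Tg libraries against -0.17, 0.04 and 0.14 in control, and that 28, 28 and 29 genes fell without Fosl2 Tg library 1, 2 and 3. A larger share of cells that did not respond to the stimulation stays open: 19 of 26 activation genes lay above the cell cycle median by more than 2 SE, but 11 fell and 2 rose, 7 of 24 naive genes rose and 0 fell, and levels in unstimulated cells, on which the fall of an activation gene depends, were not at hand. A later entry into division and a direct effect of Fosl2 on proliferation may also account for the pattern, and neither was tested.

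Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. Every split other than the real one mixes the 2 groups, so their difference enters the estimate of spread. Few called genes are then expected, and the counts below do not measure how many calls arise by chance. Fosl2 Tg against control gave 2440 called genes, against at most 2 in any other split (1 split as large, the real one), and 6 called lists against at most 8 (5 splits as large). The libraries labelled Fosl2 KO against control gave 461 genes against at most 2 (1 split) and 7 lists against at most 7 (2 splits). Fosl2 Tg against the libraries labelled Fosl2 KO gave 3943 genes against at most 3 (1 split) and 8 lists against at most 7 (1 split).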
